A study of Homo sapiens with 9 samples.

How the data were processed

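Gene expression was measured in human T cells with an Affymetrix whole-genome expression array, in 9 arrays that form 3 groups of 3. Per the labels, RNA was isolated with RNeasy kits and was amplified and labelled with biotin before hybridisation. The deposited values are intensities on a linear scale, 1 for each of 54675 probe sets in each array. The labels name GCRMA, a method that corrects background by probe sequence and summarises probes, as the authors' tool, without a version or a list of steps. The deposited intensities reach down to near 0 and differ in their quantiles between arrays, so scaling between arrays does not show in them. The median intensity per array ranged from 33.6 to 39.5 in activated microgravity, from 27.6 to 32.7 in activated 1g and from 45.2 to 56.8 in non-activated cells. No count or depth stands behind an array value, and the number of arrays limits the precision.

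The comparisons, tests, gene lists, rule for named genes and alternatives were fixed before the data were examined, with the exceptions named here. The fixed plan took the table to be normalized between arrays. Because the array medians differed, quantile normalization of all probe sets was made the main scaling before any test was run, and the values as deposited became the alternative. Values under 1 were set to 1, and log2 was taken. Of the probe sets, 41097 carried 1 gene symbol, 1801 carried several and 11777 carried none, and the last 2 classes were not used for genes. Symbols were updated through Entrez identifiers for 99.9% of the 1-symbol probe sets. The 59 sex-linked probe sets left out were not analysed here. Each of 19740 genes was represented by its probe set with the highest mean, and 16953 genes with at least 3 of 9 arrays above log2 4 (16 linear units) were tested. Another probe set above that limit existed for 8306 of them. Folds against a group whose mean lay under log2 4 were computed with that limit as floor and are given as "at least".

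The 3 comparisons were fitted in limma 3.58.1 (R 4.3.3; the data.table package, version 1.17.8) as group means over all 9 arrays, with moderated two-sided tests without trend or robust options (6 residual and 1.85 prior degrees of freedom). A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The errors printed are standard errors (SE) of the limma fit, with n = 3 arrays per group. A rank test of 3 arrays against 3 cannot give an exact p under 0.1. The 27 gene lists held 615 genes, of which 535 were measured, and were tested with camera (preset correlation 0.01), with camera and an estimated correlation, and with fry. The lists overlap, so a gene can count in several. For each list the members were also counted with p adjusted over the list alone. Genes that differed between the mean of both activated groups and the non-activated group were then compared between microgravity and 1g as a set. In this balanced design that choice of genes does not bias the second comparison. With an activated array left out, or with array weights, the design is no longer balanced and the choice does bias it. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

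The genes named are the 12 largest rises and the 12 largest falls per comparison among called genes whose groups did not overlap. Where fewer than 5 genes passed, the 10 with the smallest p were taken. For the shares, the 10 raised and 5 lowered genes with the smallest p in microgravity against 1g were taken. Any list member could also be named, and those given here were picked after their values were seen. HLA, immunoglobulin, T cell receptor segment and other genes that differ between persons were not named.

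The series design implies that the groups hold cells of the same donors, a pairing that the main fit does not use. The labels number the replicates without saying that a number is a donor. The residuals of arrays with the same number were therefore correlated across genes. Between activated microgravity and activated 1g, r was 0.11, 0.11 and 0.12, each the highest for its array between these 2 groups. Different numbers gave negative r there. That follows on average from positive same-number r, since the residuals of a group cancel, and adds no evidence of pairing. With the non-activated arrays, same-number r was 0.15, 0.02 and 0.02 for microgravity and 0.04, -0.02 and -0.09 for 1g. Non-activated replicate 2 instead had r of 0.11 with replicate 3 of both activated groups. The numbers were thus read as pairs only between the activated groups. The planned fit with the replicate number as a block nevertheless covers all arrays, and its results are given for all comparisons. Against non-activated cells that block is not shown to adjust for donors, so calls lost with it there do not test pairing. A paired fit of the 6 activated arrays was added after the residuals were checked. The block and the paired fit leave fewer residual degrees of freedom than the main fit, and camera with an estimated correlation depends on these. A call lost in these fits can reflect lower power and does not show that a difference is absent.

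The alternatives were the replicate block, the deposited scale, median centring, no limit on dim genes or a limit at log2 6, leaving out probe sets ending in _x_at or _s_at, trend and robust options, array weights, a floor at log2 4, fits of only 2 groups, other thresholds, all probe sets and leaving out each array. On simulated data of 16953 genes, with 68, 66 and 66 genes changed by log2 1, 2 and 4, the fit recovered 14.7%, 71.2% and 86.4% of them for 1g against non-activated. For microgravity against non-activated it recovered 27.9%, 68.2% and 90.9%. For microgravity against 1g it recovered 23.5%, 71.2% and 86.4%. False calls numbered 5, 6 and 13. In 50 simulations without a difference, the shares averaged 50.1% and 50.0%, and fry gave p under 0.05 in 8% and 10% of them, so it was somewhat liberal. A simulated list lowered by 1 was called, as were 2 of 26 other lists. Gene spans from RefSeq annotation (assembly GRCh38.p14), available for 99.9% of genes tested, served only as a length. The series' own labels give no genome build, and no coordinates are reported.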

Results

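The arrays measured RNA of human T cells from volunteers, flown to the International Space Station. The cells were loaded, in RPMI medium with 10% serum, into LYCIS flight hardware. On board they were kept in KUBIK, an incubator with static positions, where cells stay in microgravity, and a centrifuge that applies 1g. After 30 min of pre-incubation, activated cells received concanavalin A, a lectin that stimulates T cells, and, per the treatment protocol, an antibody to the costimulatory receptor CD28, for 1.5 h. The sample characteristics name an antibody to CD2 instead, so the labels disagree on the antibody. One activated group stayed static (activated microgravity) and the other on the centrifuge (activated 1g). Non-activated cells stayed static and were fixed after the pre-incubation. Each group held 3 arrays, described as biological triplicates with the cells of each donor kept apart. The 3'/5' signal ratio of GAPDH, a sign of RNA quality, lay between 1.58 and 2.22 in activated microgravity, between 1.62 and 1.89 in activated 1g and between 1.49 and 2.07 in non-activated cells. For ACTB the ratio lay between 2.43 and 3.27 in activated microgravity and between 2.37 and 2.86 in activated 1g. In non-activated cells the ACTB ratio lay between 2.40 and 3.50. Whether RNA quality affected the comparisons was not tested.

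Activated 1g against non-activated cells asks which genes respond to activation under gravity. The groups also differ in gravity and in time before fixation. Immediate early transcription factors were among the largest rises. EGR3 rose 98.1-fold (log2 difference 6.62 ± 0.28 SE, limma adjusted p = 0.000225) and EGR1 57.9-fold (5.85 ± 0.39). The nuclear receptors NR4A1, NR4A3 and NR4A2 rose at least 182-fold, 96.7-fold and 12.9-fold. The NR4A3 mean in non-activated cells lay near the dim limit (4.04), and with a floor at log2 4 its fold was 78.7. TNF, a proinflammatory cytokine, rose 19.4-fold (4.28 ± 0.52), and CCL20, a chemokine, rose at least 101-fold. CCL20 varied widely in non-activated cells (SD 2.15), and without a floor its log2 difference ran from 7.07 to 8.99 with an array left out. BCL2A1, an inhibitor of apoptosis, rose 19.0-fold (4.25 ± 0.39), and FOS, an AP-1 subunit, 14.6-fold (3.87 ± 0.62).

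By list, 15 of 33 immediate early genes rose over all genes tested and 23 adjusted over the list alone, with a median log2 difference of 1.67. Among them MYC rose by 2.38 ± 0.23, IER3 by 2.73 ± 0.19 and JUNB by 1.75 ± 0.19. Of 29 REL/NF-kB genes, 9 rose and 18 adjusted over the list alone (median 1.23), among them NFKBID (3.25 ± 0.23), an inhibitor of the pathway, and IRF4 (2.86 ± 0.27), a lymphocyte transcription factor. Of 24 cytokines and chemokines, 4 rose and 12 adjusted over the list alone (median 1.59). IFNG, the interferon gamma gene, stood at 4.71 ± 1.03 (adjusted p = 0.0775) and IL2, the T cell growth factor, at 2.90 ± 1.09 (adjusted p = 0.213). Of 21 surface activation markers, ICOS rose (2.24 ± 0.33), and 9 did so adjusted over the list alone (median 0.41). CD69, an early activation marker, stood at 1.71 ± 0.32 (adjusted p = 0.0564). These 4 lists were called with both forms of camera, at adjusted p = 0.0124, 0.0233, 0.0233 and 0.0357 with an estimated correlation. On the other scales these 4 lists were called only with the preset correlation, with adjusted p of 0.106 to 0.362 (deposited) and 0.0670 to 0.0758 (median-centred) with an estimated correlation. Of 18 cAMP/CREB targets, 4 rose, and adjusted over the list alone 9 rose and 1 fell (median 0.89, adjusted p = 0.0618 with an estimated correlation). Of 18 calcineurin/NFAT genes, 2 rose, and adjusted over the list alone 5 rose and 1 fell (median 0.26, adjusted p = 0.0983 with an estimated correlation). Of 30 T cell receptor signalling components, 0 passed over all genes and 1 rose adjusted over the list alone (median 0.25, adjusted p = 0.326 with an estimated correlation). The list of 28 quiescence and naive T cell genes was called lower (median -0.35) with 0 members passing either way (adjusted p = 0.298 with an estimated correlation). That call was lost on the deposited and median-centred scales (adjusted p = 0.486 and 0.531), where the median relative to the median gene was -0.08, against -0.31 with quantile scaling. Outside these lists, PTPN6, a phosphatase, rose by 2.24 ± 0.19, IL2RG, a cytokine receptor chain, by 1.68 ± 0.18, and AKT1, a kinase, by 1.51 ± 0.21. Camera called none of the 7 lists of other cell types. Fry called erythroid markers higher (adjusted p = 0.0236), among which HBD, a globin gene dim in non-activated cells, rose. With the preset correlation camera called NK markers higher on the deposited scale (adjusted p = 0.00354) and granulocyte markers lower on the median-centred scale (adjusted p = 0.0373), neither with an estimated correlation (adjusted p = 0.679 and 0.281).

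Dim genes were among the others. TMEM88, POLM and ZNF658 rose at least 8.19-fold, 3.22-fold and 1.65-fold. In 11 of the 12 largest falls the 1g mean lay under log2 4. OR1G1 was at least 3.01-fold lower, SNORD114-3 at least 2.49-fold, TP53TG3HP at least 1.85-fold, TMEM178A at least 1.75-fold, GAL3ST3 at least 1.68-fold, and LINC01012 and AMER2 each at least 1.56-fold. SMAD3-DT, YAE1-DT, SIX3 and FAM170B were at least 1.48-fold, 1.33-fold, 1.26-fold and 1.24-fold lower. SPG21 was 3.52-fold lower (-1.82 ± 0.32), while its other probe set did not go the same way. In all, limma called 178 of 16953 genes, 136 higher and 42 lower, and the groups did not overlap for 26.5% of genes, where chance gives 10%. On the deposited scale, where the median of all genes shifted by -0.53, the count was 667, with 56 higher and 611 lower, so directions hold relative to the median gene. Leaving out activated microgravity replicate 3 gave 161 genes and leaving out any other array 42 to 104.

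Activated microgravity against non-activated cells asks which genes respond to activation without gravity. The groups differ also in time before fixation. NR4A1 rose at least 9.93-fold, EGR3 11.4-fold (3.51 ± 0.28, limma adjusted p = 0.0220), NR4A3 9.52-fold (3.25 ± 0.43) and EGR1 8.41-fold (3.07 ± 0.39). For NR4A3 the fold was 7.76 with a floor at log2 4, and of its 2 other probe sets only 1 went the same way. ANK3, a membrane skeleton adaptor, rose 8.28-fold (3.05 ± 0.38), EHBP1 6.29-fold (2.65 ± 0.28), ADK, adenosine kinase, 4.91-fold (2.30 ± 0.30) and RASEF 4.87-fold (2.28 ± 0.28). PTPN6 rose by 1.60 ± 0.19, IL2RG by 1.51 ± 0.18 and AKT1 by 1.50 ± 0.21. RACGAP1, which acts in cytokinesis, was 2.09-fold lower (-1.06 ± 0.14) and RTTN, a centriole gene, 1.98-fold lower (-0.99 ± 0.13). Of the 2 other RTTN probe sets only 1 went the same way.

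Among dim genes POLM, NDN and ZNF658 rose at least 3.67-fold, 1.60-fold and 1.45-fold, and OR5H1 rose with both means under log2 4. TRIM2, SLC6A17 and FAM20C were at least 4.39-fold, 3.68-fold and 2.21-fold lower. Without probe sets ending in _x_at or _s_at, TRIM2 stood at 0.38. BCL2A1 stood at 2.26 ± 0.39 (adjusted p = 0.0828), IRF4 at 1.52 ± 0.27 (adjusted p = 0.0845), TNF at 1.10 ± 0.52 (adjusted p = 0.420) and IL2, dim in microgravity, at -0.84 ± 1.09 (adjusted p = 0.799). Of 33 immediate early genes, 4 rose and 8 adjusted over the list alone (median 0.44, adjusted p = 0.233 with an estimated correlation). Of 29 REL/NF-kB genes, 0 passed over all genes and 8 rose adjusted over the list alone (median 0.51, adjusted p = 0.233 with an estimated correlation). Cytokines (median 0.41, adjusted p = 0.298 with an estimated correlation) had 0 members passing either way. Integrated stress and unfolded protein response genes (median 0.25) had 0 members over all genes and 1, ASNS (0.97 ± 0.20), adjusted over the list alone, with adjusted p = 0.519 with an estimated correlation. Heat shock genes (median 0.16) had 0 over all genes and 2 adjusted over the list alone, HSPA6 (2.29 ± 0.51) and HSPB1 (1.84 ± 0.44), with adjusted p = 0.680 with an estimated correlation. The cAMP/CREB list (median 0.13) had 2 members higher, and 4 higher and 1 lower adjusted over the list alone, with adjusted p = 0.519 with an estimated correlation. Quiescence genes (median -0.27) and mRNA decay regulators (median -0.14) were called lower with 0 members passing either way, at adjusted p = 0.519 and 0.298 with an estimated correlation. These 8 lists were called with the preset correlation. Of all 27 lists tested, the number called was 3 without activated microgravity replicate 3 (all higher) and 3 without non-activated replicate 2 (2 higher and 1 lower). The calls of quiescence genes and mRNA decay regulators were lost on the deposited and median-centred scales (adjusted p between 0.0994 and 0.132), and that of heat shock genes on the deposited scale (adjusted p = 0.115).

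Limma called 41 genes in this comparison, 36 higher and 5 lower, and the groups did not overlap for 20.2% of genes, where chance gives 10%. Without non-activated replicate 2 the count was 30 and without any other array 0 to 23, and on the deposited scale, where the median of all genes shifted by -0.44, it was 1 gene, lower. Of the genes higher in this and the previous comparison (36 and 136), 33 were shared, where independent lists would share 0.289. The non-activated arrays are common to both comparisons. In either direction 36 genes were called in both. Simulations with shared arrays and no effect gave 0, but without an effect hardly any gene can be called at all. They therefore do not show how many shared calls the common arrays add. The correlation of differences across genes was 0.657, against 0.498 in simulations with no effect, and genes are not independent replicates.

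**Figure D1:**
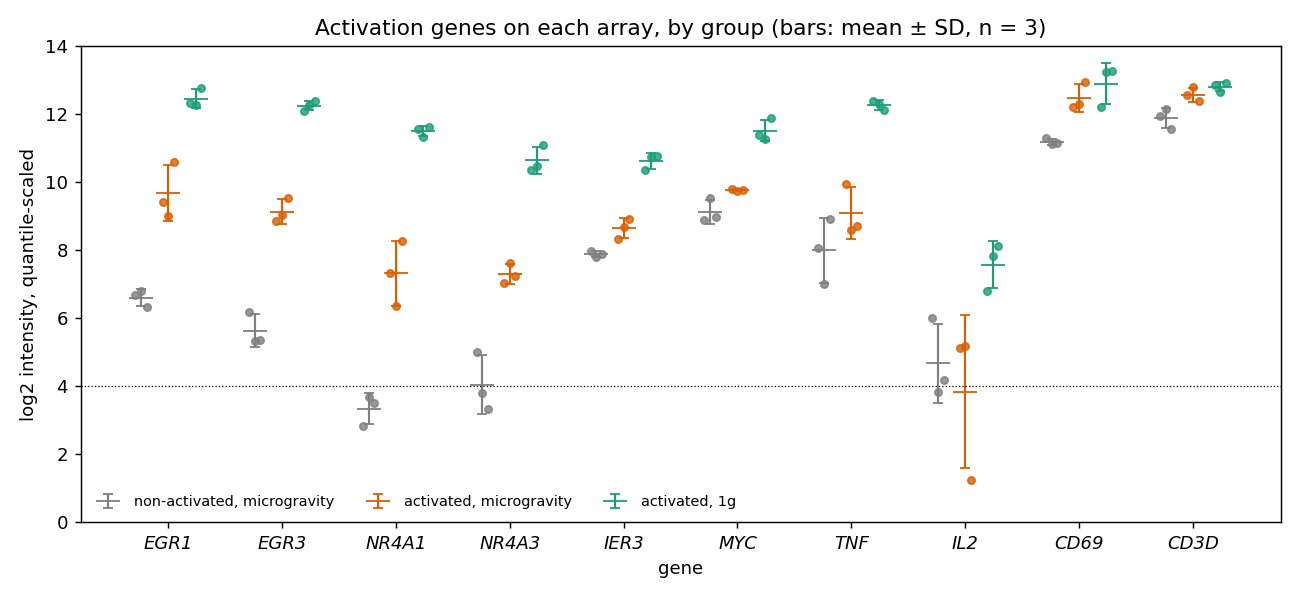
Quantile-normalized log2 intensity of named genes in each of the 9 arrays, with points for arrays and bars for the group mean and its SD (n = 3 per group). EGR3 lay between 8.85 and 9.53 in activated microgravity and between 12.10 and 12.38 in activated 1g.

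Activated microgravity against activated 1g asks whether the response differs with gravity, at the same stimulus and time. EGR3, an early transcription factor, was 8.63-fold lower in microgravity (-3.11 ± 0.28, limma adjusted p = 0.0358). IER3, an immediate early NF-kB target, was 3.92-fold lower (-1.97 ± 0.19, adjusted p = 0.0467). SNORD114-3, a small nucleolar RNA, was at least 1.73-fold higher (adjusted p = 0.00165) and YAE1-DT, a non-coding transcript, at least 1.42-fold higher (adjusted p = 0.0477), both with 1g means under log2 4.

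Other genes among the smallest p did not pass. NR4A1 stood at -4.19 ± 0.45 (adjusted p = 0.0516), but its probe set left without those ending in _x_at or _s_at gave 0.02. NFKBID stood at -2.03 ± 0.23, SHCBP1L, a dim gene, at -0.75 with a floor at log2 4, NR4A2 at -2.44 ± 0.29, DUSP2 at -1.64 ± 0.21 and MAFF at -1.44 ± 0.18. TNF stood at -3.18 ± 0.52 (adjusted p = 0.174). IL2, with a microgravity mean of 3.84, under the dim limit, stood at -3.73 ± 1.09 (adjusted p = 0.681), not an exact difference and smaller in size with a floor at log2 4. Without activated microgravity replicate 3 IL2 stood at -2.43 and without replicate 2 at -4.40. CD69 stood at -0.42 ± 0.32 and CD3D, a T cell receptor chain, at -0.24 ± 0.19. AKT1 stood at -0.01 ± 0.21, IL2RG at -0.17 ± 0.18.

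All 10 lists called were lower in microgravity. Of 33 immediate early genes 29 had lower values, 2 passed over all genes and 23 adjusted over the list alone (median -1.17, adjusted p = 0.00474 with an estimated correlation). Of 29 REL/NF-kB genes, 1 passed and 8 adjusted over the list alone (median -0.66, adjusted p = 0.0158 with an estimated correlation). Cytokines had 0 and 7 (median -0.85, 0.00930), surface activation markers 0 and 5 (median -0.54, 0.00930), calcineurin/NFAT genes 1 and 2 (median -0.31, 0.00930), cAMP/CREB targets 0 and 7 (median -0.73, 0.0183) and JAK-STAT feedback genes 0 and 1, the kinase PIM3 (median -0.19, 0.0158). The values in these brackets are adjusted p with an estimated correlation. Calls lost with it were those of dendritic cell markers (median -0.37, adjusted p = 0.0589 with an estimated correlation), early MYC and ribosome biogenesis genes (median -0.13, adjusted p = 0.117 with an estimated correlation) and p53 targets (median -0.12, adjusted p = 0.114 with an estimated correlation). The cytokine, surface and JAK-STAT lists shared 0 members with the immediate early list, so removing shared members could not test them. Without their shared members (1 of 29 and 2 of 18), the REL/NF-kB and NFAT lists each had adjusted p = 0.0295 with an estimated correlation. Without 6 of 18 members, cAMP/CREB targets gave 0.142 and were not called with it. On the deposited scale all 7 lists were called only with the preset correlation (adjusted p between 0.198 and 0.367 with an estimated correlation). With median centring this held for cAMP/CREB targets (adjusted p = 0.0678 with an estimated correlation), and dendritic cell markers were not called (adjusted p = 0.0853).

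Lists of other cell types were tested beside these groups. Of 16 NK and cytotoxic markers 15 had lower values in microgravity (median -0.55), which did not pass (adjusted p = 0.0713, and 0.711 with an estimated correlation). The paired fit of the 6 activated arrays called these markers lower with the preset correlation (adjusted p = 1.7e-06), and gave adjusted p = 0.411 with an estimated correlation. On the deposited scale they were also called lower (adjusted p = 0.00787, and 0.686 with an estimated correlation). Medians were -0.25 for erythroid, -0.09 for B cell, 0.09 for platelet and 0.13 for granulocyte markers, and -0.07 for monocyte markers, whose test went the other way. Granulocyte markers were called higher on the deposited and median-centred scales with the preset correlation (adjusted p = 0.0380 and 0.0341, and 0.217 and 0.261 with an estimated correlation). T cell receptor components had a median of -0.04 (adjusted p = 0.0933). Relative to the median gene it was -0.19 on the deposited and median-centred scales, where the list was called with the preset correlation (adjusted p = 0.637 and 0.322 with an estimated correlation). Other lists not called in the fit of 9 arrays had medians of 0.36 for interferon-stimulated, 0.13 for cell cycle, 0.13 for integrated stress, 0.06 for heat shock, 0.02 for quiescence, -0.02 for mTORC1, -0.06 for SRF/MRTF, -0.07 for mRNA decay and -0.10 for hypoxia genes. Of these, the paired fit called interferon-stimulated genes higher and hypoxia genes lower with the preset correlation (adjusted p = 0.614 and 0.418 with an estimated correlation). Hypoxia genes were also called lower on the deposited and median-centred scales (adjusted p = 0.654 and 0.331 with an estimated correlation), as were mRNA decay regulators (adjusted p = 0.637 and 0.293 with an estimated correlation). Ribosomal protein genes had a median under 0.01 in size, with mean and test of opposite sign.

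In all, limma called 4 genes here, 2 higher and 2 lower, with 979 at an unadjusted p under 0.05, and the groups did not overlap for 11.1% of genes, where chance gives 10%. With the replicate number as a block no gene was called by limma (1104 at an unadjusted p under 0.05), nor in the paired fit of the 6 activated arrays (1094), where EGR3 had adjusted p = 0.478. With the block 8 of the 10 lists were called and none with an estimated correlation (immediate early genes, adjusted p = 0.0511). The paired fit called 12 lists, 1 of them higher, and none with an estimated correlation (immediate early genes, adjusted p = 0.291). Both fits leave fewer residual degrees of freedom, so these losses cannot be told apart from lower power. Without activated 1g replicate 2 the count was 16, of which 12 were higher, and it was 1 without any of activated microgravity replicate 1, activated 1g replicates 1 and 3 or non-activated replicates 2 and 3, and 2 without activated microgravity replicate 2. Median centring gave 7 genes, 2 higher and 5 lower. The calls of SNORD114-3 and YAE1-DT were lost with a floor at log2 4 (10 genes) and with trend and robust options (18 genes), and both fell outside the test with a dim limit at log2 6 (13 genes). All genes called in these 3 settings were lower.

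**Figure D2:**
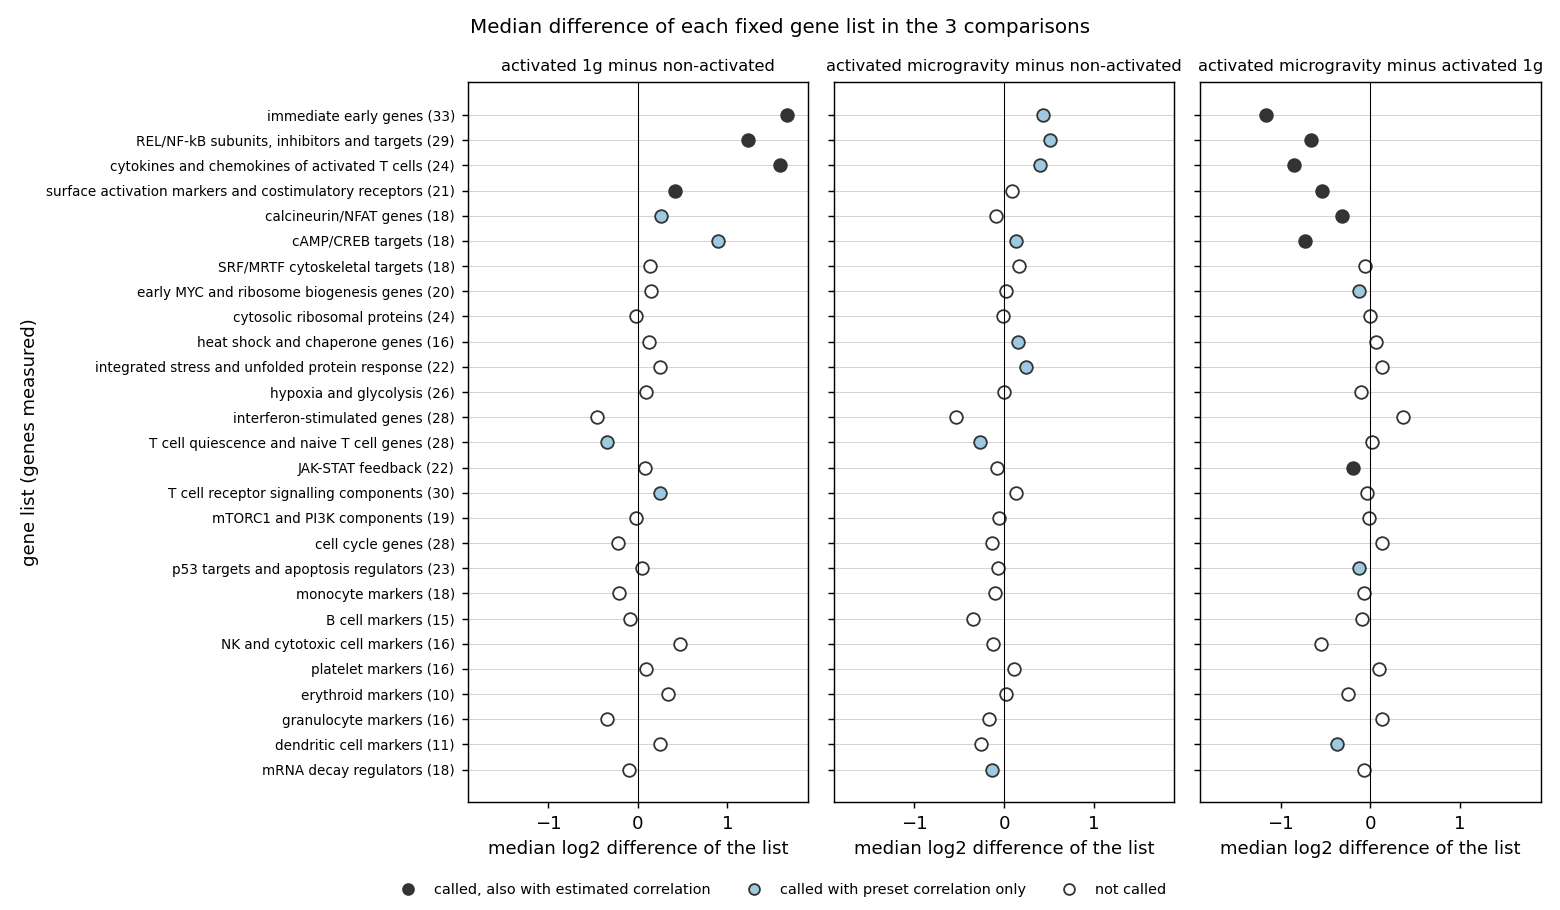
Median log2 difference of the measured members of each of the 27 gene lists, with 1 panel per comparison and the number of genes in brackets. In microgravity minus 1g the immediate early list lay lowest, at -1.17. Dark points mark lists called with both forms of camera, light blue points those called with the preset correlation only, and open points those not called.

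The next comparison asks whether genes that respond to activation respond less in microgravity. Against non-activated cells, the mean of both activated groups was higher for 167 genes and lower for 44. With an array left out these counts were 49 to 121 and 2 to 29, and on the deposited scale 12 and 11, so the genes behind the shares change with the setting. Of the 167 raised genes, 122 (73.1%) had lower values in microgravity than in 1g, with median responses of 1.16 and 1.35 (fry p = 0.000519, and p = 0.00371 from camera with an estimated correlation). The raised genes with the smallest p were EGR3, IER3, NR4A1, NFKBID, NR4A2, MAFF, NR4A3 (-3.34 ± 0.43), MYC (-1.75 ± 0.23), KLF10 (-1.95 ± 0.27) and JUNB (-1.36 ± 0.19). In a division chosen after the values were seen, 19 raised genes stood on the 6 activation lists. All 19 had lower values in microgravity, with a median response of 1.10 against 2.86 in 1g. Of the other 148, 103 (69.6%) had lower values, with medians of 1.16 and 1.23.

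Of the 44 lowered genes, 25 (56.8%) had higher values in microgravity (median difference 0.02, fry p = 0.00131, and p = 0.177 from camera with an estimated correlation). The 5 lowered genes with the smallest p were all dim. With a floor at log2 4, SNORD114-3 stood at 0.79, SLC6A17 at -1.25 and TRIM2 at -1.01, and without probe sets ending in _x_at or _s_at TRIM2 stood at 1.39. FAM20C and TMEM178A had both means under log2 4. The genes called lowered differ in each setting below. Leaving out an activated array also unbalances the choice of genes, which biases the share downward where that array is from microgravity. The share was 36.4% of 11 genes without activated microgravity replicate 1 and 44.8% of 29 without activated microgravity replicate 3, both with fry's direction turned, not past the threshold in the first case and past it in the other. It was 46.2% of 13 genes without activated microgravity replicate 2 and 33.3% of 6 without non-activated replicate 2, where the test was not passed. It was 43.8% of 16 genes without a limit on dim genes, 50% of 16 with median centring and 33.3% of 12 genes with at least a 2-fold mean response, with fry's direction unchanged and past the threshold.

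**Figure D3:**
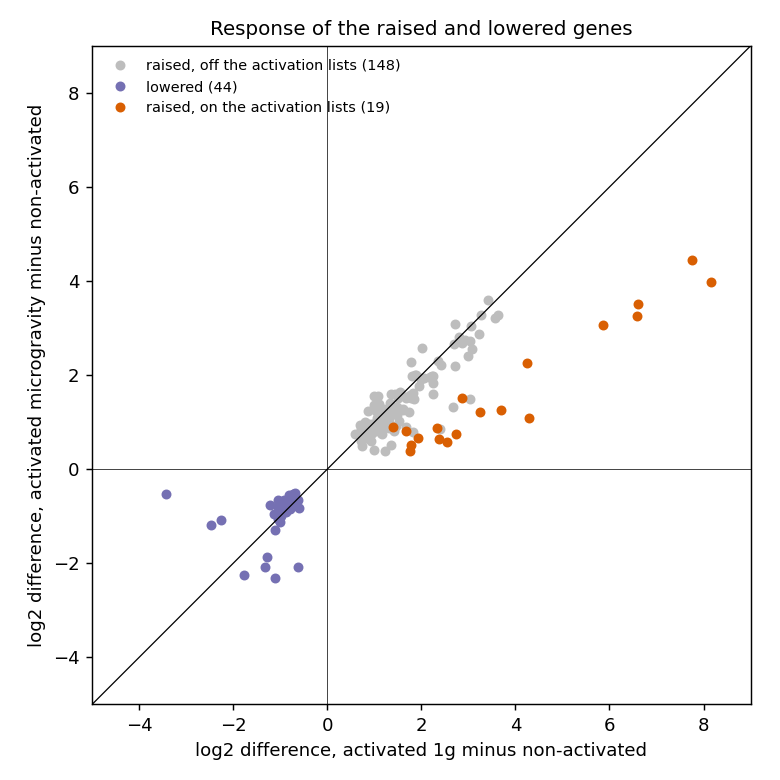
Activation response in microgravity (vertical axis) against that in 1g (horizontal axis), both in log2, for the 167 raised and 44 lowered genes. Of the raised genes 122 lie under the line of equal response, since their values were lower in microgravity.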

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

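The tests of explanations for the immediate early genes were chosen only after the result was seen, while the counts over splits of the arrays were fixed before. Each result here stands out because the activation response differed between microgravity and 1g by a test of the difference itself, with the non-activated arrays common to both. For genes the log2 difference was -3.11 for EGR3, -1.97 for IER3, 2.91 for SNORD114-3 and 3.84 for YAE1-DT, and all 4 calls were lost with the replicate number as a block. SNORD114-3 and YAE1-DT had 1g means under log2 4, so their differences are not exact, and with a floor there they were 0.79 and 0.51 and not called. For lists the median difference was -1.17 for immediate early genes, -0.66 for REL/NF-kB genes, -0.85 for cytokines and -0.54 for surface activation markers. It was -0.31 for calcineurin/NFAT genes, -0.73 for cAMP/CREB targets and -0.19 for JAK-STAT feedback genes. It was -0.13 for early MYC and ribosome biogenesis genes, -0.12 for p53 targets and -0.37 for dendritic cell markers, 3 lists not called with an estimated correlation. On the deposited scale none of the 10 was called with an estimated correlation. The same held with the replicate number as a block and in the paired fit. Both leave fewer residual degrees of freedom, so calls lost there cannot be told apart from lower power. The shares were 73.1% of raised genes lower in microgravity and 56.8% of lowered genes higher there. The second passed with fry only (p = 0.00131), with a median difference of 0.02 and p = 0.177 from camera with an estimated correlation.

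The immediate early genes had lower values in activated microgravity than in activated 1g. With an estimated correlation, camera lost this call with the replicate block (adjusted p = 0.0511) and in the paired fit (adjusted p = 0.291). These fits leave fewer residual degrees of freedom, so the loss alone cannot decide whether the difference holds under pairing. Scaling between arrays as the whole cause is argued against, since relative to the median of all genes the list's median lay at -1.17 with quantile scaling and -1.29 on the deposited scale (median centring gives the same relative value by construction), although on the deposited scale the list had adjusted p = 0.198 with an estimated correlation. Fewer T cells in the microgravity samples as the whole cause are argued against by the T cell receptor components, with a median of -0.036 (-0.19 relative to the median gene on the other scales). Of these, 30 of 30 members lay above the immediate early median, a low bar that most genes clear. Of 16 NK and cytotoxic markers 15 had lower values (median -0.55, not called in the fit of 9 arrays), and a change in the mix of cells was not tested. For a weaker or later delivery of the activators to static cells the values go both ways: raised genes outside the activation lists were also mostly lower (69.6%), but their median response was 1.16 against 1.23 in 1g, while that of listed genes was 1.10 against 2.86, which is not a loss by a like share. Since genes can differ in how they depend on dose and time, such delivery cannot be told apart from a response of the cells to gravity, which also stays open as untested, and either could account for the pattern.

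With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. For 1g against non-activated, only the real split (178 genes, 8 lists) gave as many genes or lists, and the highest of the others gave 2 genes and 7 lists. For microgravity against non-activated, only the real split (41 genes, 8 lists) did so, and the highest of the others gave 1 gene and 5 lists. For microgravity against 1g (4 genes, 10 lists), 2 splits gave as many genes, the real one included (highest other 4), and only 1, the real one, as many lists (highest other 7). Of the 10 splits, 3 gave as high a share of raised genes (highest other 74.3%) and 6 as high a share of lowered genes (highest other 61.4%). Of the 4 splits that part all 3 replicate pairs, the real one included, the others gave 0 to 1 genes, 0 to 5 lists and shares of raised genes of 55.1% to 74.3%.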

How the results depend on the processing

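The paired fit of the 6 activated arrays was chosen after the pairing check was seen, and all other alternatives were planned. The floor alternative was corrected after its counts had been seen, so that it changes no probe set. Counts below are of genes for 1g against non-activated, microgravity against non-activated and microgravity against 1g, where the main counts are 178, 41 and 4. The replicate block gave 24, 0 and 0 (limma, 2300 and 1104 at an unadjusted p under 0.05 for the last 2). It also blocks the non-activated arrays, whose numbers were not shown to match those of the activated arrays. The deposited scale gave 667 and 1, and median centring gave 18 for the second and 7 for the last. Without a limit on dim genes the counts were 111, 14 and 1, and with a limit at log2 6 they were 784, 186 and 13 (the last all lower). Without probe sets ending in _x_at or _s_at they were 87, 8 and 2. Trend and robust options gave 833, 226 and 18, and a floor at log2 4 gave 361, 74 and 10 (the last all lower in both). Array weights gave 8 for the last. Fits of only 2 groups gave 56, 0 and 0 (2008 and 909 at an unadjusted p under 0.05). The paired fit gave 0 for the last (1094 at an unadjusted p under 0.05). Unadjusted p with a 2-fold difference gave 930, 553 and 417. Testing all probe sets gave 25 for the second and 11 for the last. Leaving out each array gave 42 to 161, 0 to 30 and 1 to 16 genes. The limit on signal over background moved all 3 counts, and a higher limit tests fewer genes by construction. The cause of the moves was not tested.

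For lists the main counts are 8, 8 and 10. The deposited scale gave 14 and 5 for the first comparisons, median centring gave 14 for the first, and leaving out _x_at and _s_at probe sets gave 3 for the second. An estimated correlation gave 4 and 0, and fry gave 3 for the second. With the replicate block, the 4 lists of the first comparison had adjusted p of 0.0751 to 0.181 with an estimated correlation. In that comparison the block is not shown to adjust for donors. Leaving out each array gave 8 to 10, 3 to 8 and 9 to 12, with 3 for the second without activated microgravity replicate 3 or non-activated replicate 2. The genes counted in the shares, 167 raised and 44 lowered in the main setting, are called anew in each setting, so the shares are not over the same genes. The replicate block left 35 and 2, the deposited scale 12 and 11, and trend and robust options gave 581 and 332. Leaving out each array gave 49 to 121 and 2 to 29. Leaving out an activated array also unbalances the choice of genes and biases both shares, downward for a microgravity array and upward for a 1g array. The share of raised genes kept its direction and passed its test under each alternative (70.5% to 85.7%, the last over the 35 genes of the block, and 66.9% to 81.7% with an array left out). The share of lowered genes was 43.8% of 16 genes without a limit on dim genes, 50% of 16 with median centring, 1 of 2 with the replicate block, 33.3% of 12 at a 2-fold mean response and 53.8% to 68.1% under the other alternatives, with fry passed in its main direction. It ran from 33.3% to 75% with an array left out. It was 36.4% of 11 genes without activated microgravity replicate 1 and 44.8% of 29 without replicate 3, where fry's direction turned, without passing the threshold in the first case and passing it in the other.

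Of 145 gene values named or followed, 73 were called, and the block kept 16 of them, the deposited scale 45 of 72 and median centring 60 of 72. Called or not, these turned sign. Without _x_at and _s_at probe sets TRIM2 gave 0.38 in microgravity against non-activated and 1.39 against 1g, and NR4A1 gave 0.021 against 1g, since other probe sets stand for them. In microgravity against 1g, where it was near 0, AKT1 gave 0.037 with array weights, 0.19 without activated microgravity replicate 3, and 0.050 and 0.024 without activated 1g replicates 1 and 2 (lowest with an array left out, -0.18). PRKCB gave -0.035 there with median centring, against 0.19. IL2 in microgravity against non-activated gave 0.033 with a floor at log2 4 and 0.47 without activated microgravity replicate 3, against -0.84 (lowest with an array left out, -1.50). The cause was not tested for the last 3 genes.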

Other observations

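The choice of gene span as a property, its tests and the genes named from it were made only after the responses were seen. In the mean of both activated groups against non-activated cells, a larger share of very long genes than of shorter genes was raised. Among genes with a mean above log2 6, 30 of 232 genes over 300 kb were raised (12.9%) and 0 lowered, against 105 raised (1.14%) and 34 lowered of 9225 shorter genes. These calls are few and move, with 49 to 121 genes raised and 2 to 29 lowered in all when an array is left out, against 167 and 44. ANK3, a membrane skeleton adaptor, was 8.27-fold higher in the mean of both activated groups (log2 difference 3.05 ± 0.33 SE). HDAC4, a histone deacetylase, was 5.48-fold higher (2.45 ± 0.21), ADK, adenosine kinase, 4.99-fold (2.32 ± 0.26) and the kinase PRKCB 3.70-fold (1.89 ± 0.16). ITPR1, a calcium release channel, was 2.49-fold higher (1.32 ± 0.15) and the kinase PRKCA 2.29-fold. In microgravity against 1g, HDAC4 stood at -0.51 ± 0.24 and PRKCB at 0.19 ± 0.19, neither past the test. In shorter spans the raised share was 2.19% up to 10 kb, 1.25% from 10 to 30 kb, 0.384% from 30 to 100 kb and 1.09% from 100 to 300 kb. Of 10000 random lists matched for mean level, none held more than 12 raised genes. Such lists take genes as independent and cannot allow for a property chosen after the responses were seen. They are therefore no test of the pattern.

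A hypothesis is that activation within 1.5 h raises the array signal of some very long genes. Whether full-length transcripts of these genes were made was not measured. A first test, on the gap between the medians of long and other genes, gave only 0.09 with quantile scaling and on the deposited scale, under its bound of 0.1, so the typical long gene was not higher by that bound, and it was replaced by the tests on shares. By array, against the mean of the non-activated arrays, this gap ran from 0.040 to 0.204 in activated cells. In non-activated cells it ran from -0.031 to 0.042, so the arrays overlapped. Scaling between arrays is argued against by the share of long genes among the 1% of genes with the highest response, 6.90% with quantile scaling and 6.61% on the deposited scale, against 0.86% of other genes in both (median centring gives the same ranks as the deposited scale). Probe sets on unspliced or intronic sequence are argued against as the whole cause by a raised share of 16.4% among the 67 long genes with RefSeq transcript targets. A longer time in culture before fixation could also account for the pattern and cannot be told apart from activation, since no group was kept unactivated for the full time, and the 30 genes differed little between microgravity and 1g (median -0.074).

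Several lists had medians, means and tests that differ in sign, none of them called in that comparison by either test. With camera and fry both read, these were B cell markers, platelet markers (fry only) and mTORC1 genes in 1g against non-activated, calcineurin/NFAT, hypoxia and JAK-STAT feedback genes (the last in fry only) in microgravity against non-activated, and monocyte markers and ribosomal proteins in microgravity against 1g. Interferon-stimulated genes had medians of -0.45 in 1g and -0.54 in microgravity against non-activated cells, with an estimated correlation between members of 0.708. Of the 19 lists that camera did not call in 1g against non-activated, its lowest adjusted p with the preset correlation was 0.0538, for integrated stress genes (median 0.24) and for cell cycle genes (median -0.22). Fry called 4 of these 19, with JAK-STAT feedback, erythroid and early MYC genes higher (adjusted p = 0.00883, 0.0236 and 0.0263) and cell cycle genes lower (adjusted p = 0.0140). With the preset correlation, camera called integrated stress, hypoxia, JAK-STAT feedback, early MYC and ribosomal protein genes higher on both other scales, cell cycle genes lower on the deposited scale and heat shock genes higher with median centring. None of these passed with an estimated correlation. In microgravity against non-activated it called ribosomal protein genes higher with median centring only (adjusted p = 1.7e-06, and 0.798 with an estimated correlation).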
